A study of Mus musculus with 9 samples.

How the data were processed

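RNA was measured in the peri-infarct region, the tissue bordering the infarct, of mouse hearts 4 weeks after an infarct made by tying off the left anterior descending coronary artery. The mice were female, 80 to 100 days old and of a SCID strain, which lacks functional T and B lymphocytes. They had been injected with saline, with cardiomyocytes differentiated from induced pluripotent stem cells (iCM) or with exosomes, small vesicles that cells release, precipitated from such cardiomyocytes (iCM-Ex). The labels give 3 biological replicates per group, each on its own array, 9 arrays in all. The species of the stem cells and the time of day of tissue collection are not given in the sources used here. Total RNA was extracted, and 5.5 µg of cDNA per sample was labelled for Clariom S arrays, which carry 1 summarised probe set for most genes, per the labels' protocols.

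The deposited values are the authors' log2 signals, 1 per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. The version of that program and its methods of background correction and normalisation are not given in the sources used here. The log2 scale was read from the values, which lay between 2.25 and 19.93 on the 9 arrays. At the upper end, 10 genes came within 0.01 of the highest value on at least 1 array. Dcn and Nppa, named for this after their values were seen, did so on all 3 iCM-Ex arrays, so their iCM-Ex levels are lower bounds. The number of arrays limits the precision of every value below.

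The value table held 28846 rows, of which 6640 were controls (1324 positive, 5222 negative, 23 background, 63 spike-in and 8 others). Of the 22206 gene rows, 19572 had 1 gene symbol in the annotation used, none had several and 2634 had none. All 19572 were matched to the gene table by Entrez identifier, and 0 symbols needed updating. For the 55 genes with more than 1 row the row with the highest mean over all arrays was kept, which left 19505 genes. Rows without a symbol entered none of the gene comparisons reported as results, only the alternative with all rows but controls and a separate count of such rows past the threshold. Control rows served only for control separation. No further normalisation or filter was applied before the comparisons. As a measure of array quality, the median log2 signal of the positive control probe sets minus that of the negative ones was computed for each array and is called control separation below. Median negative controls averaged 5.29 in saline, 5.31 in iCM and 4.86 in iCM-Ex. They are not a floor, since the lower quartile of gene signals was 4.03 to 4.31 on the arrays. A group mean below them lies near background, and the size of a change from or to it is uncertain.

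The comparisons were fixed before the data were examined. All 9 arrays entered 1 limma fit with a mean for each group, followed by empirical Bayes moderation (prior degrees of freedom 4.23, residual degrees of freedom 6). The contrasts were iCM minus saline, iCM-Ex minus saline and iCM-Ex minus iCM, each tested on both sides, with a moderated F test of any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over the 19505 genes within a contrast, and the threshold was an adjusted p of 0.05. Changes are differences of mean log2 signal with their moderated standard error (SE), and levels are means with the standard deviation (SD) of 3 arrays. Because each gene was measured on 3 arrays per group, an exact permutation test of a single value cannot give a p below 0.1.

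Gene lists were written from textbook knowledge before the data were examined, with the study's interest in autophagy known. The 43 lists of processes and of cell types that a dissected piece of heart could hold named 917 genes, of which 834 were measured. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 43 lists. Camera with a correlation estimated for each list, and fry, which asks whether the members move one way or in either direction without regard to other genes, were run as alternatives. Members were also counted with limma p-values adjusted over the list alone. The value after ± beside a list median is a standard error over the member genes, taken as independent. It does not measure the spread between arrays.

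The genes named in the text were chosen by a rule fixed beforehand. For each contrast these were the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups. Predicted genes, olfactory receptors and vomeronasal receptors were counted but not named. Of each list, up to 4 members past the threshold adjusted over the list alone were added, or else the 2 members with the smallest p. Genes named outside this rule are said to be so.

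The fit was tested on simulated data with the spread of the real genes, with 50 genes changed at each of 4 sizes. For iCM minus saline, 4% of changes of 1 log2 unit were recovered, 60% of those of 2, 78% of those of 3 and 94% of those of 4, and 7 unchanged genes were called. For iCM-Ex minus saline the shares were 2%, 62%, 82% and 96%, with 7 unchanged genes called. For iCM-Ex minus iCM they were 6%, 62%, 88% and 90%, with 8 unchanged genes called. In a simulated iCM group, a list of 39 genes raised by 1 log2 unit was recovered by camera with 0 other lists past the threshold. The simulated genes were drawn independently, so this cannot show how often camera at the preset correlation calls unchanged lists of correlated genes.

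Alternatives planned beforehand were the replicate number as a block, leaving out each array in turn, filters on dim genes at the 25th percentile and at the median, a common array median, quantile normalisation, moderation with a trend and robust variances, array weights, fits of only the groups compared, the mean of all rows of a gene, all rows but controls, and other thresholds. Added after the data were seen were leaving out saline replicate 1 and iCM replicate 2 together, leaving out the 3 arrays with lung, muscle or fat markers together, and control separation as a covariate. To measure what the shared saline arrays alone produce, 100 data sets with 3 unchanged groups were simulated. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.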

Results

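Whole-transcriptome signals were measured in the peri-infarct region of 9 mouse hearts 4 weeks after infarction, in 3 hearts each injected with saline, with stem-cell-derived cardiomyocytes (iCM) or with exosomes from these cells (iCM-Ex). After adjustment over 19505 genes, 716 genes differed between iCM and saline, 68 between iCM-Ex and saline and 208 between iCM-Ex and iCM by limma. The F test of any difference among the groups called 647 genes. That count fell to 43 without saline replicate 2 and to 92, 146, 192, 330 and 405 without iCM-Ex replicate 3, iCM replicate 2, iCM-Ex replicate 2, iCM replicate 3 and saline replicate 1.

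Arrays of one group correlated at r = 0.943 to 0.978 across genes in saline, 0.947 to 0.950 in iCM and 0.961 to 0.981 in iCM-Ex, and at 0.898 to 0.952 between saline and iCM, 0.920 to 0.955 between iCM and iCM-Ex and 0.920 to 0.975 between saline and iCM-Ex. Median gene signals were 5.43 in saline replicate 1 and 5.64 to 5.70 on the other 8 arrays. The first principal component held 29.7% of the variance and placed the iCM arrays at 37.2 to 94.0, against −39.3 to −53.7 for saline. The second held 24.3%, and saline replicate 1 lay at 95.4 on it. Control separation was 3.44 ± 0.15 in saline, 2.94 ± 0.41 in iCM and 3.77 ± 0.21 in iCM-Ex (SD, n = 3 each). The groups did not overlap, and each exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow.

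Markers of tissues other than myocardium stood out on single arrays. These genes were singled out after their values were seen, from lists fixed beforehand. The surfactant protein gene Sftpc, a marker of alveolar lung cells, had a log2 signal of 19.53 in iCM replicate 1, 11.02 in iCM replicate 2 and 18.09 in iCM-Ex replicate 3, against at most 5.96 in saline. The fast skeletal muscle myosin gene Myh4 had a signal of 15.77 in iCM replicate 2 and of 3.41 to 5.03 on the other arrays. In the same array the fat hormone gene Adipoq reached 12.75 and the brown fat gene Ucp1 9.31, against 4.32 to 6.26 and 3.22 to 3.87 in saline. The mean of 11 lung genes was 11.24 in iCM replicate 1 and 8.37 in iCM-Ex replicate 3, and 4.29 to 5.98 elsewhere.

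**Figure D1:**
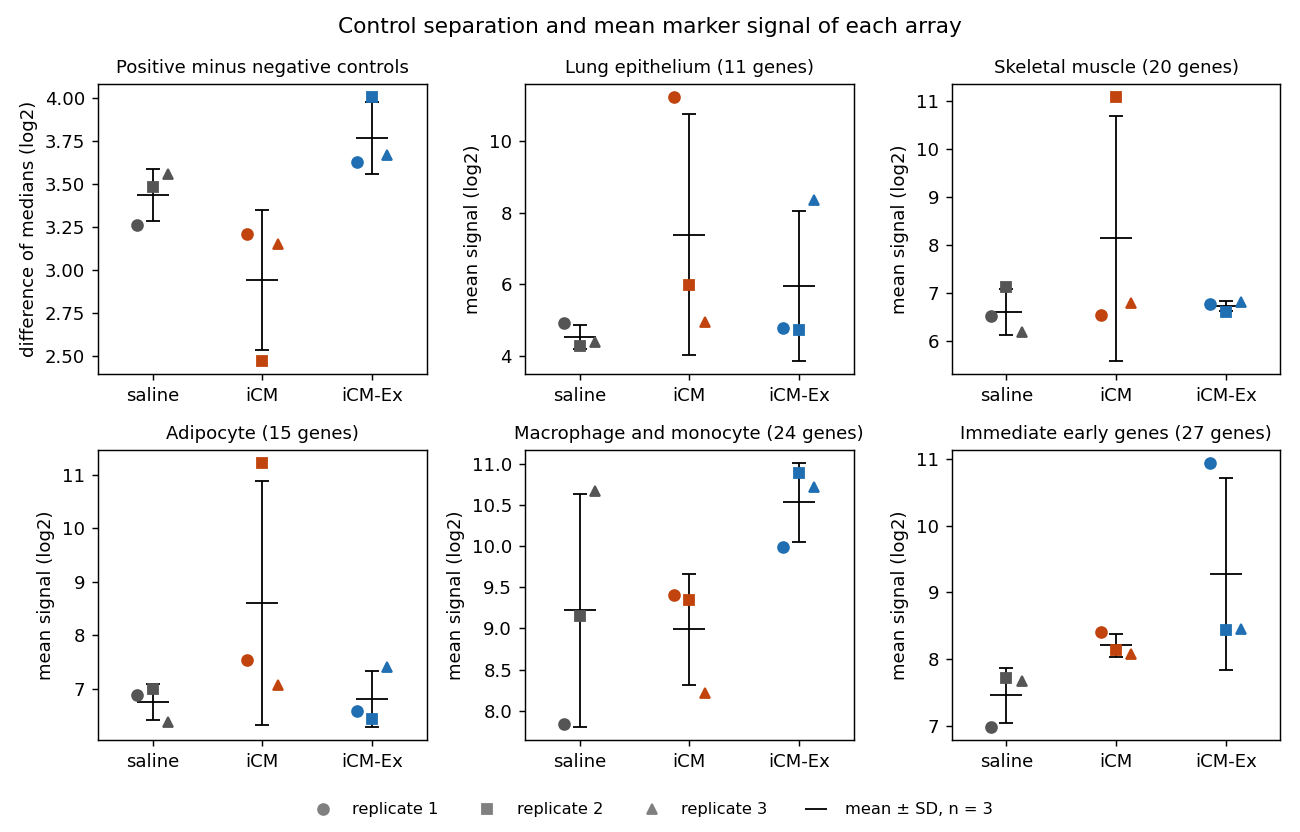
Control separation (log2 difference of medians) and mean log2 signal of 5 fixed marker lists on each array, with 1 symbol per replicate and the mean ± SD of 3 arrays per group as bars. Control separation did not overlap between groups, and the lung, skeletal muscle and adipocyte means of 11.24, 11.09 and 11.22 each belonged to 1 iCM array.

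The comparison of iCM with saline asked how the border zone differed after cell injection. Interferon-inducible genes were higher in iCM hearts. Iigp1, an interferon-induced GTPase that acts against intracellular pathogens, rose by 5.30 ± 0.76 (log2, SE), from 7.41 ± 0.66 to 12.71 ± 1.68 (SD, n = 3; limma adjusted p = 0.00889). The related GTPase genes Tgtp2, Igtp and Irgm1 rose by 5.17, 5.08 and 4.30, and the guanylate-binding protein gene Gbp4 rose by 4.54. Of 25 measured interferon-response genes 22 were higher, with a median of 1.305 ± 0.34. Over all genes 4 rose (Iigp1, Igtp, Zbp1 and Gbp3), and 7 rose when adjusted over the list alone. Zbp1 lay below the median negative control in saline, at 4.25. Camera gave an adjusted p of 2.84e-05, and adjusted p = 0.701 with an estimated correlation. The list's mean was 8.89, 7.36 and 9.32 on the iCM arrays against 6.51, 6.60 and 7.87 in saline, and its median was 0.68 without iCM replicate 3. Iigp1 stayed past the limma threshold whichever array was left out, with a highest adjusted p of 0.0471. Without saline replicate 2 the limma adjusted p was 0.0692 for Tgtp2, 0.0661 for Igtp, 0.0605 for Gbp4, 0.0586 for Irgm1, 0.0818 for Zbp1 and 0.103 for Gbp3.

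Dad1, a subunit of the enzyme complex that attaches N-linked glycans, fell by 6.35 ± 0.67, from 17.99 ± 0.81 to 11.64 ± 1.29 (limma adjusted p = 0.00397). The extracellular antioxidant enzyme gene Gpx3 fell by 3.51 ± 0.39 and the muscle LIM protein gene Fhl1 by 3.06 ± 0.37. Hspb6, a small heat shock protein of muscle, fell by 5.90, and its limma adjusted p was 0.0742 without saline replicate 2. Tuba1a, which encodes a tubulin, fell by 4.45, and the complement inhibitor gene Cd59a fell by 4.52. The carbonic anhydrase gene Car4 rose by 3.96 ± 0.39 (limma adjusted p = 0.00325). Of the 65 named genes past the threshold in this contrast, 12 stayed past it whichever array was left out. These were Car4, Cd59a, Dad1, Dpagt1, Fhl1, Gpx3, Iigp1, Mcoln1, Mpv17, Tmem47, Tnnt1 and Tuba1a.

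Fibroblast and matrix genes were lower in iCM hearts. Of 31 measured genes of fibrillar collagens and extracellular matrix 28 were lower (median −1.09 ± 0.22), as were 20 of 23 fibroblast markers (median −1.19 ± 0.28). Over all genes 1 member of each list fell, the elastin gene Eln, from 12.74 to 9.74, and the secreted chaperone gene Clu, which fell by 3.51 ± 0.60. Adjusted over the list alone, 3 and 2 members fell. Camera gave an adjusted p of 0.000192 for each, and adjusted p = 0.701 with an estimated correlation. Both lists stayed past the threshold whichever array was left out, but their medians moved. The matrix median was −1.64 without saline replicate 1, −0.69 without saline replicate 2 and −0.62 without iCM replicate 3, and the fibroblast median −1.87 without iCM replicate 1 and −0.76 without iCM replicate 3. Fibroblast markers had a mean signal of 12.85, 11.31 and 11 on the iCM arrays and of 12.16, 13.56 and 13.17 in saline, beside the lower control separation of the iCM arrays. For single members, limma adjusted p was 0.0644 for Clu and 0.125 for Eln without saline replicate 2. With control separation as a covariate, a fit added after the data were seen, the fibroblast median was −0.81 and its camera adjusted p 0.0576.

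Lysosomal genes were lower, with a median of −0.58 ± 0.31 over 25 measured members. Of these 4 fell over all genes, and 9 fell and 1 rose when adjusted over the list alone. The lysosomal calcium channel gene Mcoln1 fell by 2.87, the cathepsin A gene Ctsa fell by 3.31, and the acid alpha-glucosidase gene Gaa fell from 12.11 to 9.91. Camera gave an adjusted p of 0.0103 for the list, 0.0759 without saline replicate 3 and adjusted p = 0.701 with an estimated correlation. Its median was −0.32 without saline replicate 3, −0.87 without saline replicate 1, −0.31 under quantile normalisation (adjusted p = 0.15) and 0.009 with control separation as a covariate (0.138), and its adjusted p was 0.207 among genes above the median. Without saline replicate 2 limma adjusted p was 0.0605 for Gaa and 0.0954 for Ctsa. Among angiogenesis genes Vegfa, which encodes the main endothelial growth factor, rose by 2.05. The Notch receptor gene Notch1, Vegfb and the endoglin gene Eng fell by 1.80, 2.79 and 2.89. The size of the Notch1 fall is uncertain, since its iCM mean of 4.05 lay below the median negative control. Of the 27 measured angiogenesis genes 17 were lower (median −0.375 ± 0.34, camera adjusted p = 0.046), and 2 rose and 5 fell when adjusted over the list alone. Adjusted p was 0.701 with an estimated correlation, and 0.0709, 0.158, 0.164 and 0.0964 without saline replicates 2 or 3 or iCM replicates 2 or 3. The angiogenesis median lay between −0.69 (without iCM replicate 1) and −0.25 (without iCM replicate 3). The highest limma adjusted p of the 4 genes on leaving out an array was 0.0908 for Vegfa, 0.0747 for Notch1 and 0.131 for Eng (without saline replicate 2) and 0.0881 for Vegfb (without iCM replicate 2).

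Lists of adipocyte, lung and skeletal muscle genes were also past the threshold, and each rested on the arrays named above. The adipocyte median was 1.94 ± 0.33 over 15 members (camera adjusted p = 0.00288), and 0.42 without iCM replicate 2 (adjusted p = 0.24). Fabp4, a fatty acid carrier of fat and capillary endothelium, was the member that rose, by 2.91 (limma adjusted p = 0.0988 without saline replicate 2). The skeletal muscle median was 1.54 ± 0.44 over 20 members (camera adjusted p = 0.0149), and 0.29 without iCM replicate 2 (adjusted p = 0.596). Without saline replicate 3 its adjusted p was 0.0971. The slow troponin gene Tnnt1 was the member that rose, by 2.57. It was at 7.76, 9.25 and 8.32 on the iCM arrays against 5.68, 5.84 and 6.10 in saline, so its rise did not rest on 1 array. The lung median was 2.60 ± 0.76 over 11 members (camera adjusted p = 0.0149) with 0 members past the limma threshold over all genes or over the list alone. It was 0.70 without iCM replicate 1 (adjusted p = 0.334), and its adjusted p was 0.0507 without saline replicate 3. Each of these lists had adjusted p = 0.701 with an estimated correlation.

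The other 6 lists past the camera threshold each lost it on removal of 2 to 4 of the arrays, taken singly. Adjusted over the list alone, limma called 5 fallen and 1 risen tricarboxylic acid cycle genes, 5 fallen oxidative stress genes, 3 risen neutrophil genes, 1 fallen smooth muscle gene and none of the TGF-beta and immediate early genes. Tricarboxylic acid cycle genes had a median of −0.78 ± 0.38 (adjusted p = 0.013), and Pdha1, a subunit of pyruvate dehydrogenase, fell by 2.90. The adjusted p was 0.169, 0.16 and 0.0867 without saline replicate 1, iCM replicate 1 and iCM replicate 2. TGF-beta signalling genes had a median of −0.59 ± 0.26 with 0 members called by limma (adjusted p = 0.0382, and 0.0814, 0.169 and 0.118 without saline replicates 2 and 3 and iCM replicate 3). Smooth muscle genes had a median of −0.49 ± 0.24 and Smtn, a smooth muscle cytoskeletal gene, fell by 1.52 (adjusted p = 0.046, and 0.173, 0.215 and 0.0523 without saline replicate 3 and iCM replicates 2 and 3). Oxidative stress defence genes had a median of −0.19 ± 0.32, which turned to 0.02 under quantile normalisation, and Gpx3 was the member that fell over all genes. Their adjusted p was 0.0485, and 0.0528, 0.123, 0.0613 and 0.174 without saline replicates 1 and 3 and iCM replicates 1 and 2. Immediate early genes had a median of 0.60 ± 0.22 (adjusted p = 0.0444, and 0.172 and 0.16 without saline replicate 1 and iCM replicate 1). Neutrophil genes had a median of 0.63 ± 0.52 (adjusted p = 0.0444, and 0.0684, 0.0623 and 0.133 without saline replicates 1 and 2 and iCM replicate 2). The calprotectin gene S100a9 rose by 3.20 from 4.97, below the median negative control, so the size of its rise is uncertain. With an estimated correlation each adjusted p lay between 0.701 and 0.789. Over the arrays left out the medians ranged from −1.32 to −0.43 for the tricarboxylic acid cycle, −0.86 to −0.21 for TGF-beta, −0.875 to −0.295 for smooth muscle, −0.53 to −0.07 for oxidative stress and 0.39 to 0.86 for immediate early genes. On leaving out an array the highest limma adjusted p was 0.097 for Pdha1 (saline replicate 2), 0.151 for Smtn and 0.0996 for S100a9 (iCM replicate 2).

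In total 262 genes rose and 454 fell in iCM relative to saline, so that 36.6% of the calls were higher. The median size of the called changes was 2.04. The groups' arrays did not overlap for 24.0% of all genes, against an expectation of 10% by chance. Genes are correlated and the spread of that expectation over splits was not measured, so this share is no test. Quantile normalisation gave 418 rises and 442 falls. The count was 126 without saline replicate 2, 196 without iCM replicate 2, 423 without saline replicate 3, and 462 and 436 without iCM-Ex replicates 2 and 3. Without the 3 arrays with lung, muscle or fat markers 6 genes were past the threshold, 5 of them among the 716. With control separation as a covariate the count was 33. Of the 716 genes, 114 had a group mean below the median negative control, 26 of them in both groups. Besides lysosomal genes, the tricarboxylic acid cycle, TGF-beta, smooth muscle, angiogenesis and oxidative stress lists lost their camera call under quantile normalisation (adjusted p = 0.195, 0.189, 0.201, 0.216 and 0.541) and among genes above the median (0.129, 0.299, 0.475, 0.475 and 0.475), and neutrophil genes under quantile normalisation (0.0568). With the covariate 6 lists were past the threshold, and most of the 14 lists called without it were not among them.

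**Figure D2:**
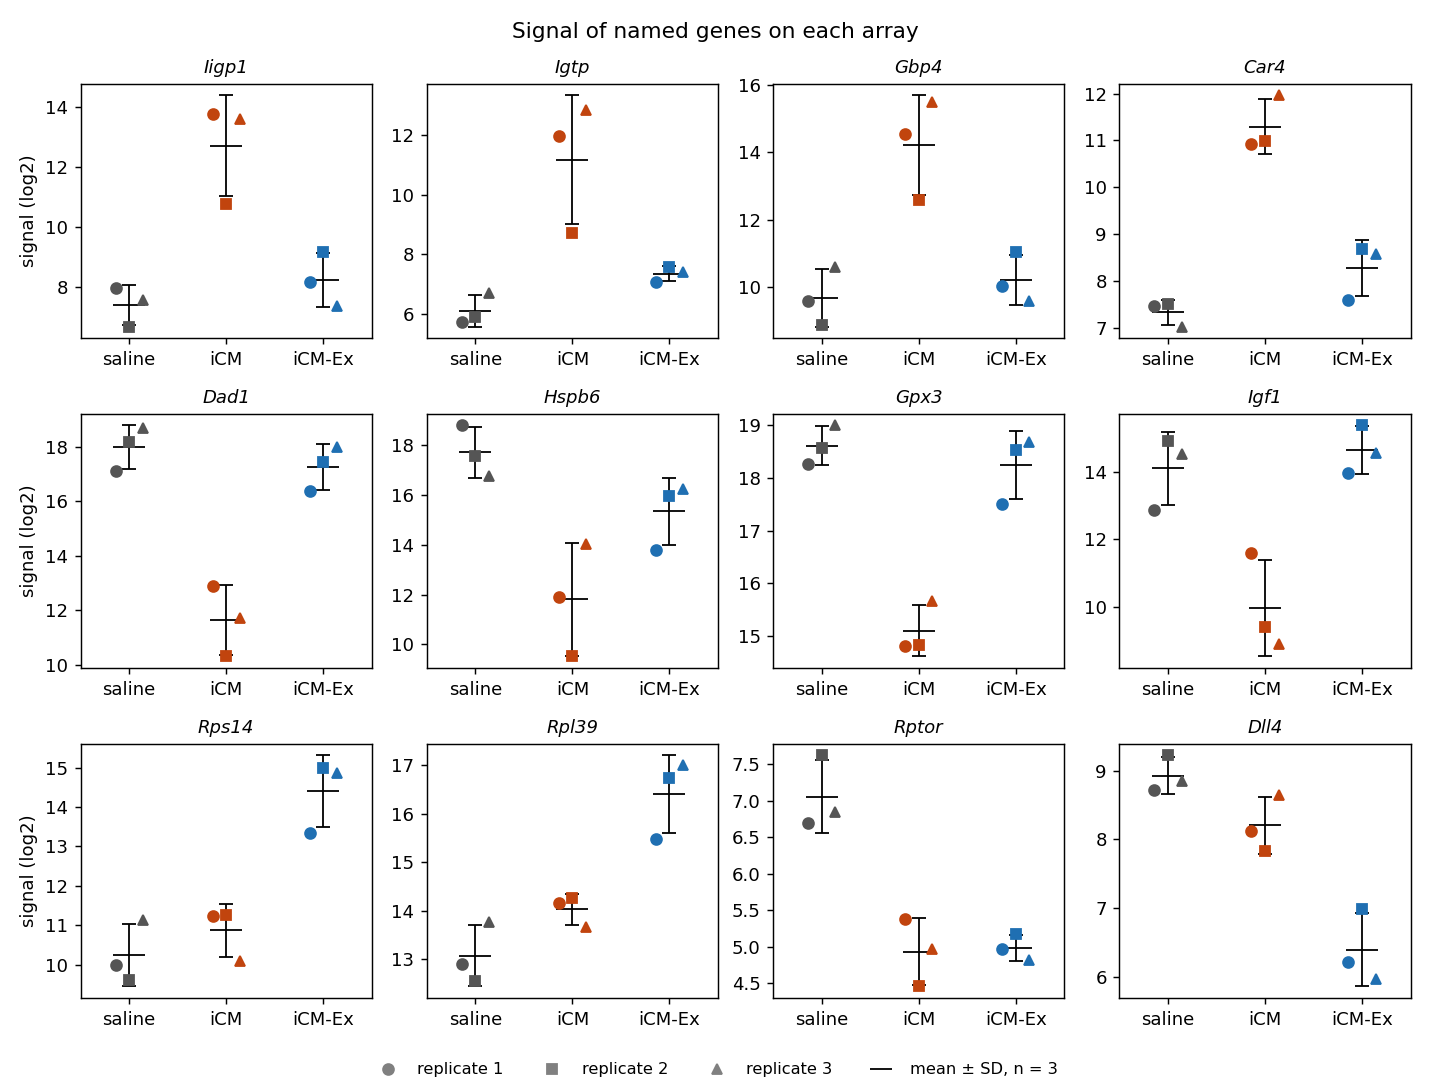
Log2 signal of 12 named genes on each array, with 1 symbol per replicate and the mean ± SD of 3 arrays per group as bars. Iigp1, Igtp, Gbp4 and Car4 were highest in iCM, Dad1, Hspb6, Gpx3 and Igf1 lowest in iCM, and Rps14 and Rpl39 highest in iCM-Ex, where Rpl39 averaged 16.41 against 13.08 in saline.

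The comparison of iCM-Ex with saline asked how the border zone differed after exosome injection. Genes of cytosolic ribosomal proteins, the protein components of the translation machinery, were higher in iCM-Ex hearts. Rps14 rose by 4.15 ± 0.55 (log2, SE) to 14.40 ± 0.92, and Rpl39 rose by 3.33 ± 0.45, from 13.08 ± 0.63 to 16.41 ± 0.80 (SD, n = 3; limma adjusted p = 0.0291 for each). Of 27 measured ribosomal genes 25 were higher with a median of 1.73 ± 0.26, 7 rose over all genes and 21 when adjusted over the list alone. The camera adjusted p was 1.22e-18, and adjusted p = 0.57 with an estimated correlation. The list's mean was 14.89, 15.62 and 15.69 on the iCM-Ex arrays, 13.02, 13.65 and 14.12 in saline and 14.11, 13.63 and 13.46 in iCM. Control separation was likewise higher in every iCM-Ex array, at 3.63, 4.01 and 3.67 against 3.26, 3.48 and 3.56 in saline. The list stayed past the threshold under each alternative run with the preset correlation, while limma adjusted p was 0.173 for Rps14 and for Rpl39 without iCM-Ex replicate 3.

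The largest falls outside predicted genes were those of the proteasome subunit gene Psmd7 (by 2.98 ± 0.46), Phxr4 (by 2.80 ± 0.31), Apbb2 and Zfp46. Dll4, the Notch ligand of sprouting endothelium, fell by 2.54 ± 0.35 (limma adjusted p = 0.0291), and Hipk2, a nuclear kinase, fell by 2.56. Without iCM-Ex replicate 3 limma adjusted p was 0.202 for Psmd7 and Hipk2, 0.173 for Phxr4, 0.237 for Apbb2 and 0.188 for Dll4, and without saline replicate 2 it was 0.182 for Zfp46. Angiogenesis genes had a median of −0.45 ± 0.22, with 17 of 27 lower, Dll4 fallen over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00294, and adjusted p = 0.66 with an estimated correlation). Calcium handling and ion channel genes had a median of −0.74 ± 0.23, with 23 of 26 lower, 0 past the limma threshold over all genes and 6 fallen when adjusted over the list alone (camera adjusted p = 1.57e-06, and adjusted p = 0.57 with an estimated correlation). The calcium handling median was −1.245 without saline replicate 3, and the angiogenesis median −0.28 without iCM-Ex replicate 1. Among the 6 calcium handling genes were the potassium channel genes Kcnq1 (−1.98) and Kcnh2 (−2.48) and the L-type calcium channel gene Cacna1c (−2.70).

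Immediate early genes, which are induced within minutes of a stimulus, were higher in iCM-Ex hearts, with 26 of 27 members above saline and a median of 1.86 ± 0.28. None was past the limma threshold over all genes, and 10 rose when adjusted over the list alone (camera adjusted p = 8.57e-10, and adjusted p = 0.57 with an estimated correlation). The list's mean was 10.95 in iCM-Ex replicate 1, 8.43 and 8.45 in the other iCM-Ex arrays and 6.98 to 7.71 in saline. Chosen after the values were seen, Nr4a1 was at 14.45 and Nr4a3 at 14.58 in iCM-Ex replicate 1, against 6.73 and 6.52 in replicate 2 and 6.61 and 5.70 in replicate 3. Without that array the median was 0.68 and the camera adjusted p 1.06e-06. Inflammatory cytokine genes had a median of 1.85 ± 0.36, with 27 of 29 higher, 0 past the limma threshold over all genes and 4 adjusted over the list alone, the monocyte attractants Ccl8 (5.30), Ccl2 (3.23), Ccl7 (2.17) and Ccl6 (2.87). For the cytokine list camera's adjusted p was 1.57e-06, and adjusted p = 0.57 with an estimated correlation. The cytokine median was 0.99 without iCM-Ex replicate 1 and 1.20 without saline replicate 1.

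Macrophage and monocyte markers were higher, with 21 of 24 above saline, a median of 1.19 ± 0.26 and 0 past the limma threshold over all genes or over the list alone. Camera gave an adjusted p of 0.000355, and adjusted p = 0.793 with an estimated correlation. Without saline replicate 1 the median was 0.53 (adjusted p = 0.0702), and without saline replicate 3 it was 2.06. The list's mean was 9.99, 10.89 and 10.72 on the iCM-Ex arrays and 7.84, 9.15 and 10.67 in saline. Complement and antigen presentation genes had a median of 1.32 ± 0.32, with 19 of 22 higher, 0 over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000227, and adjusted p = 0.73 with an estimated correlation). Without saline replicate 1 the complement median was 0.845. Those 4 were the class II genes H2-Ab1 (2.45), H2-Eb1 (3.96) and H2-DMb1 (2.57) and the immunoproteasome gene Psmb8 (1.86).

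Of the other lists past the camera threshold, tricarboxylic acid cycle genes had a median of −0.67 ± 0.26 (adjusted p = 0.00294, and 0.121 without saline replicate 1) and glycolysis genes of −0.49 ± 0.23 (adjusted p = 0.0178, and 0.0765 and 0.0634 without saline replicate 1 and iCM-Ex replicate 3). Neutrophil genes had a median of 0.69 ± 0.42 (adjusted p = 0.0179, and 0.0619 without iCM-Ex replicate 1). Erythroid and platelet genes had a median of 1.19 ± 0.70 (adjusted p = 0.0181, and 0.0702 and 0.0554 without saline replicate 1 and iCM-Ex replicate 2). Mast cell genes had a median of 0.56 ± 0.26 (adjusted p = 0.0366, and 0.0702, 0.0964, 0.052 and 0.0656 without saline replicates 1 and 3, iCM replicate 1 and iCM-Ex replicate 2). Adult sarcomere genes had a median of −0.51 ± 0.28 (adjusted p = 0.0465), with adjusted p between 0.052 and 0.358 without saline replicate 1 or 2, iCM replicate 1 or 2 and iCM-Ex replicate 2 or 3. Oxidative phosphorylation genes had a median of 0.31 ± 0.17 (adjusted p = 0.0465), with adjusted p between 0.058 and 0.651 without saline replicate 2 or 3, iCM replicate 2 and iCM-Ex replicate 2 or 3. In these 7 lists limma called 0 members over all genes, and adjusted over the list alone 0 to 3 rose and 0 to 3 fell. With an estimated correlation each adjusted p lay between 0.57 and 0.903. Over the arrays left out the medians ranged from −1.03 to −0.20 for the tricarboxylic acid cycle, −0.69 to −0.31 for glycolysis, 0.66 to 1.10 for neutrophil, −0.74 to −0.03 for sarcomere and 0.045 to 0.625 for oxidative phosphorylation genes.

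In total 43 genes rose and 25 fell in iCM-Ex relative to saline, so that 63.2% of the calls were higher, with a median size of 2.34. The groups' arrays did not overlap for 21.7% of all genes, against an expectation of 10% by chance, which again is no test. With arrays shifted to a common median 43 rose and 38 fell. Limma called 0 genes without saline replicate 2, iCM replicate 3, iCM-Ex replicate 2 or iCM-Ex replicate 3, where unadjusted p was below 0.05 for 2273, 3012, 2693 and 1915 genes. With control separation as a covariate it called 5, and without the 3 arrays with lung, muscle or fat markers 0 (1911 unadjusted). It called 1 without saline replicate 1, 12 without iCM replicate 1, 31 without iCM replicate 2 and 163 without saline replicate 3. Among genes above the median, the angiogenesis, glycolysis, sarcomere and oxidative phosphorylation lists had camera adjusted p of 0.0644, 0.0782, 0.124 and 0.0511, and oxidative phosphorylation had 0.0538 under quantile normalisation and 0.297 with the covariate. Of the 68 genes, 9 had a group mean below the median negative control. Of the 23 named genes past the threshold, each lost its call on removal of at least 1 array.

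**Figure D3:**
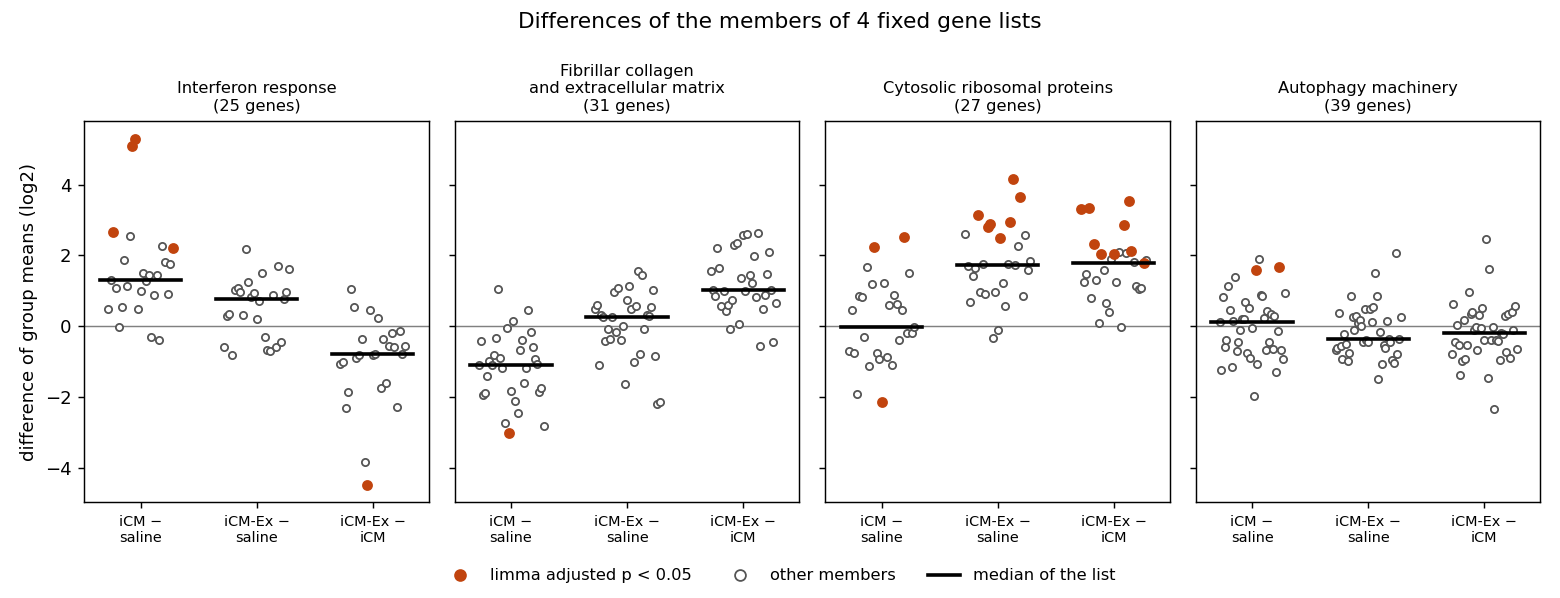
Difference of group means (log2) of each member of 4 fixed lists in the 3 contrasts, with filled points past the limma threshold over all genes, open points for the other members and bars at the list medians. Ribosomal protein genes had medians of 1.73 and 1.79 in the contrasts of iCM-Ex with saline and with iCM, interferon-response genes of 1.305 in iCM against saline, and autophagy genes spread on both sides of 0.

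The comparison of iCM-Ex with iCM asked where exosomes and the cells that released them left different profiles. Dad1 rose by 5.62 ± 0.67 and Tuba1a by 5.51 ± 0.61 in iCM-Ex relative to iCM (log2, SE; limma adjusted p = 0.0126 and 0.0125), opposite in sign to their falls in iCM relative to saline, which rest on the same iCM arrays. The insulin-like growth factor gene Igf1 rose by 4.68 ± 0.73, from 9.96 ± 1.43 to 14.64 ± 0.71 (SD, n = 3; limma adjusted p = 0.0275). The natriuretic peptide gene Nppb, a marker of ventricular wall stress, rose by 3.19 ± 0.40 (limma adjusted p = 0.0126). The interferon-inducible genes Iigp1 and Gbp4 fell by 4.47 and 4.01, Irgm1 fell by 3.49, and Xdh, which encodes xanthine dehydrogenase, fell by 3.10. Without iCM-Ex replicate 2 limma adjusted p was 0.0903 for Dad1 and 0.0919 for Nppb. Without iCM-Ex replicate 3 it was 0.085 for Tuba1a, 0.152 for Igf1, 0.19 for Iigp1, 0.205 for Gbp4 and Irgm1 and 0.13 for Xdh.

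Ribosomal protein genes were higher in iCM-Ex than in iCM, with 26 of 27 above and a median of 1.79 ± 0.22. Over all genes 9 rose, among them Rpl6 by 2.03, Rps14 by 3.53 and Rpl10a by 3.30, and 21 rose when adjusted over the list alone (camera adjusted p = 5.51e-20, and adjusted p = 0.544 with an estimated correlation). Fibroblast markers had a median of 1.36 ± 0.31, with 20 of 23 higher, 0 past the limma threshold over all genes and 8 when adjusted over the list alone (camera adjusted p = 4.42e-06). Matrix genes had a median of 1.01 ± 0.20, with 28 of 31 higher and 0 past either limma threshold (camera adjusted p = 2e-05). Relative to saline the iCM-Ex medians were 0.32 for fibroblast and 0.26 for matrix genes (camera adjusted p = 0.841 and 0.944). Both differences from iCM thus mirror the falls in iCM relative to saline, on the same iCM arrays. Macrophage markers had a median of 1.73 ± 0.43, with 17 of 24 higher, 0 over all genes, and 6 risen and 1 fallen when adjusted over the list alone (camera adjusted p = 0.00012). Among the 6 were Fcer1g (5.28) and the chemokine receptor gene Cx3cr1 (3.55, of uncertain size, from an iCM mean of 4.63, below the median negative control). Each of these had adjusted p = 0.544 with an estimated correlation, and control separation differed between the groups by 0.83. With it as a covariate the fibroblast median was 0.59 (camera adjusted p = 0.156). The matrix median was 1.55 and 0.57 without iCM replicates 1 and 3 and 0.57 without iCM-Ex replicate 1. Without iCM-Ex replicate 3 limma adjusted p was 0.205 for Rpl6, 0.16 for Rps14 and 0.152 for Rpl10a.

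Interferon-response genes had a median of −0.79 ± 0.32, with 21 of 25 lower, Iigp1 fallen over all genes and 5 when adjusted over the list alone (camera adjusted p = 0.00028). Endothelial markers had a median of −0.88 ± 0.28, with 16 of 20 lower (camera adjusted p = 0.00123). The water channel gene Aqp1 fell by 2.09 over all genes, and 5 fell and 1 rose when adjusted over the list alone. Calcium handling genes had a median of −0.57 ± 0.21, with 24 of 26 lower and 0 past either limma threshold (camera adjusted p = 0.000529). Oxidative stress defence genes had a median of 0.71 ± 0.28, with 18 of 23 higher (camera adjusted p = 0.000289). The peroxidase genes Gpx3, Gpx1 and Prdx1 rose by 3.14, 3.58 and 1.81 over all genes, and 4 members rose when adjusted over the list alone. Inflammatory cytokine genes had a median of 1.07 ± 0.35 with 0 past either limma threshold (camera adjusted p = 0.000313). Lysosomal genes had a median of 0.52 ± 0.23, with Atp6v0d1, a proton pump subunit gene, 2.19 higher over all genes and 5 risen when adjusted over the list alone (camera adjusted p = 0.00128). Unfolded protein response and heat shock genes had a median of 0.61 ± 0.26, with the chaperone gene Hsp90aa1 2.95 higher over all genes, and 3 risen and 1 fallen when adjusted over the list alone (camera adjusted p = 0.00166). Each of these lists had adjusted p = 0.544 with an estimated correlation. Relative to saline, only the calcium handling and cytokine lists among them were past the camera threshold in iCM-Ex. There the interferon, endothelial, oxidative stress, lysosomal and unfolded protein medians were 0.78, −0.05, 0.27, −0.01 and 0.22 (camera adjusted p = 0.129, 0.241, 0.376, 0.88 and 0.46). With control separation as a covariate the oxidative stress, cytokine and lysosomal medians were 0.39, 0.80 and 0.11 (camera adjusted p = 0.138, 0.156 and 0.503), and the unfolded protein median reversed to −0.33 (0.496). Lysosomal and unfolded protein genes lost their camera call under quantile normalisation (adjusted p = 0.0971 and 0.0677) and among genes above the median (0.0574 and 0.0564). The interferon median was −1.28 and −0.27 without iCM replicates 2 and 3, and without iCM replicate 3 the endothelial median was −0.48, the calcium handling median −0.36 and the cytokine median 0.64. The cytokine median was 0.42 without iCM-Ex replicate 1, the unfolded protein median 0.20 without iCM replicate 2 and the lysosomal median 0.79 without iCM replicate 1. Without iCM-Ex replicate 3 limma adjusted p was 0.205 for Aqp1, Gpx1 and Prdx1 and 0.168 for Atp6v0d1, and without iCM-Ex replicate 2 it was 0.0919 for Gpx3 and 0.0843 for Hsp90aa1.

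Each of the other 6 lists past the camera threshold lost its call on removal of 1 to 3 of the arrays, taken singly. The adipocyte median was −1.70 ± 0.25 (adjusted p = 9.97e-05) and −0.36 without iCM replicate 2 (adjusted p = 0.0696). The skeletal muscle median was −1.275 ± 0.38 (adjusted p = 0.0153) and −0.04 without iCM replicate 2 (adjusted p = 0.914). Immediate early genes had a median of 0.97 ± 0.20 (adjusted p = 0.000163) and were not past the threshold without iCM-Ex replicate 1 (median 0.175, adjusted p = 0.27). Complement genes had a median of 0.74 ± 0.35 (adjusted p = 0.0166, and 0.104, 0.329 and 0.0824 without iCM replicates 2 and 3 and iCM-Ex replicate 2). TGF-beta genes had a median of 0.59 ± 0.27 (adjusted p = 0.0241, and 0.169 and 0.225 without iCM replicate 3 and iCM-Ex replicate 1). Relative to saline the TGF-beta median in iCM-Ex was 0.02 (camera adjusted p = 0.841). Cell cycle genes had a median of 0.23 ± 0.15, and the kinase gene Cdk4 rose by 2.43 (limma adjusted p = 0.205 without iCM-Ex replicate 3; camera adjusted p = 0.0399, and 0.351 and 0.185 without iCM replicate 3 and iCM-Ex replicate 2). Over the arrays left out the medians ranged from 0.53 to 1.26 for complement, 0.40 to 0.93 for TGF-beta and 0.04 to 0.385 for cell cycle genes, and the immediate early median was 1.47 without iCM-Ex replicate 2. Over all genes limma called Cdk4 alone among these lists, and adjusted over each list alone 0 to 2 rose and 0 to 1 fell. With an estimated correlation each adjusted p lay between 0.544 and 0.663.

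In total 155 genes rose and 53 fell in iCM-Ex relative to iCM, so that 74.5% of the calls were higher, with a median size of 2.38. The groups' arrays did not overlap for 20.2% of all genes, against an expectation of 10% by chance, which is no test here either. Quantile normalisation gave 159 rises and 140 falls. Limma called 0 genes without iCM-Ex replicate 2 (2109 at an unadjusted p below 0.05), 1 without iCM-Ex replicate 3, and 26, 41 and 43 without saline replicate 2, iCM replicate 2 and iCM replicate 3. With control separation as a covariate it called 0 (1252 unadjusted), and without the 3 arrays with lung, muscle or fat markers 0 (1872 unadjusted). It called 376 without iCM replicate 1 and 401 without iCM-Ex replicate 1. Complement and TGF-beta genes had camera adjusted p of 0.0844 and 0.0677 under quantile normalisation. With the covariate cell cycle and TGF-beta genes had 0.258 and 0.493, and complement, adipocyte and skeletal muscle medians reversed to −0.186, 2.14 and 2.465 (camera adjusted p = 0.373, 0.000689 and 2.66e-07). Of the 208 genes, 107 were also called in iCM minus saline with the opposite sign and 0 with the same sign, and both contrasts use the same iCM arrays. A group mean below the median negative control was found for 9 of the 208. Of the 36 named genes past the threshold, each lost its call on removal of at least 1 array.

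The study's stated interest in autophagy and mTOR signalling was followed across the contrasts. The 39 measured genes of the autophagy machinery had medians of 0.11 ± 0.18 in iCM and −0.36 ± 0.145 in iCM-Ex relative to saline, and of −0.195 ± 0.17 in iCM-Ex relative to iCM. Camera adjusted p was 0.846, 0.137 and 0.258, and for iCM minus saline the median was positive while camera's direction was down. In iCM hearts Gabarapl1, an LC3-family gene that builds autophagosome membranes, rose by 1.59 ± 0.31 (limma adjusted p = 0.0245), and the fusion protein gene Vamp8 rose by 1.67 ± 0.39 (limma adjusted p = 0.0457). The highest limma adjusted p on leaving out an array was 0.0691 for Gabarapl1 (saline replicate 3) and 0.152 for Vamp8 (saline replicate 2). Adjusted over the list alone, 2 rose and 1 fell in iCM, 1 rose in iCM-Ex, and 3 rose and 3 fell between iCM-Ex and iCM. Fry's test of change in either direction gave adjusted p of 1.12e-05, 0.0128 and 0.000145, and 20, 12 and 11 of the 43 lists were past its threshold.

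Rptor, which encodes the raptor subunit of mTOR complex 1, fell by 2.12 ± 0.34 in iCM (limma adjusted p = 0.0133) and by 2.07 ± 0.34 in iCM-Ex (limma adjusted p = 0.0437) relative to saline, from 7.06 ± 0.50 to 4.94 ± 0.46 and 4.99 ± 0.18 (SD, n = 3). The iCM level lay below the median negative control of iCM (5.31), so the size of that fall is uncertain. The iCM-Ex level lay only slightly above that of iCM-Ex (4.86). For Rptor limma adjusted p was 0.0592 in iCM without saline replicate 2 and 0.236 in iCM-Ex without iCM-Ex replicate 3. The kinase gene Pdpk1 and the mTOR activator gene Rheb fell by 1.53 and 1.16 in iCM (limma adjusted p = 0.0897 without iCM replicate 2 and 0.121 without saline replicate 3). Relative to iCM, in iCM-Ex Rheb rose by 1.58 and Tsc1, an inhibitor of Rheb, fell by 1.47 (limma adjusted p = 0.0386 for each, and 0.205 for each without iCM-Ex replicate 3). Of 26 measured genes of the mTOR and insulin pathway, 17 were lower in iCM-Ex than in saline with a median of −0.48 ± 0.25, Rptor fell over all genes and 7 fell when adjusted over the list alone. Camera gave an adjusted p of 0.00106, and adjusted p = 0.57 with an estimated correlation. The list was not past the threshold in iCM minus saline (median −0.165 ± 0.22, adjusted p = 0.104) or in iCM-Ex minus iCM (median −0.48 ± 0.21, adjusted p = 0.145).

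Changes against saline in iCM and in iCM-Ex correlated across genes at r = 0.53, and 100 simulated sets of unchanged groups with shared saline arrays gave 0.502. The jackknife SE of r over arrays was 0.144, and genes are not independent replicates. This r therefore shows no relation beyond what the shared saline arrays alone give. The covariance was 0.308 against a simulated 0.116, a difference of 0.192. Both contrasts called 21 genes higher and 18 lower, and 0 in opposite directions. The simulated unchanged sets gave a mean overlap of 0, and independent lists of these sizes would share 0.58 genes in each direction. Neither value combines real changes with the shared saline arrays. Shared saline arrays also favour calls of the same sign, so the 0 in opposite directions decides nothing. Among the 39 were Rptor, the ribosomal genes Rps19 and Rpl37, Cox7a2 and Tnnt1. With 3 saline arrays no split into parts of at least 2 was possible, so the covariance and the overlap cannot be told apart from an effect of the shared controls.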

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

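The test of saline replicate 1, the test of lung, muscle or fat tissue and the fit with control separation as a covariate were chosen after the results were seen, while the other predictions were written before their values. The bounds of the macrophage and sarcomere tests were read more strictly after their values were seen. The standard errors in these tests and in that of short transcripts are over genes and leave out the spread between arrays.

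Probe sets without a gene symbol, left out of the gene comparisons reported as results, also carried differences between groups. Of 2634 such probe sets, limma placed 40 higher and 32 lower in iCM than in saline at an adjusted p below 0.05. For iCM-Ex relative to saline it placed 34 higher and 5 lower. The fit of all rows but controls leaves no room for so many in iCM-Ex. It called 91 rows in that contrast, 68 of them already called as genes. The counts of such probe sets thus rest on a different adjustment and cannot be set beside those of named genes. Control probe sets had a mean separation of 3.77 in iCM-Ex, and every iCM-Ex array lay above every saline array.

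Among the 10 splits of each pair of groups, the real one gave the most genes past the threshold, so 1 of 10 reached its count. The real splits gave 716, 68 and 208 genes for iCM minus saline, iCM-Ex minus saline and iCM-Ex minus iCM, and the highest others 1, 0 and 1. With 10 splits the smallest possible share is 0.1, too few to exclude chance. For the F test 1 of 100 splits of the 9 arrays, the real one, reached 647 genes, and the highest other gave 41. Chance is therefore an unlikely source of that count, though not an excluded one. Without saline replicate 2 the real count was 43.

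The pattern of 716 genes between iCM and saline was set against 3 explanations. Without saline replicate 1, 538 genes were past the threshold, 401 of them among the 716, which argues against that array as the only source. A first form of this test, on the called genes alone, was dropped because those genes had been picked for the pattern. Of 46 markers of lung epithelium, skeletal muscle and fat, 2 (Fabp4 and Tnnt1) were past the threshold, a count that excludes nothing, since a gene high on 1 of 3 arrays has too wide a spread to pass (Sftpc 12.46 ± 6.47 in iCM), while Fabp4 was at 17.29, 19.86 and 18.33 in iCM, and 18 of the 46 were above the median gene in saline and 2 stood on another list; 6 genes passed without the 3 arrays, with 1 iCM array left, so such tissue stays a possible explanation of part of the calls. Over the called genes, the change predicted from control separation correlated with the measured one at r = 0.462, below the 0.492 of the 95th percentile of permutations. With separation as a covariate their median size went from 2.04 (SE 0.377) to 1.73 (SE 0.47), with 716 signs kept and 26 calls left. Both a smaller change and a larger error ended calls. These genes were picked for large changes without the covariate, and separation did not overlap between the groups, so the kept signs and smaller size decide nothing. Lower separation may account for part of the calls, beside an effect of the injected cells.

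The higher ribosomal protein genes in iCM-Ex than in saline, with a median of 1.73, were also set against 3 explanations. A bias towards short transcripts was tested on 156 genes of mitochondrial ribosomal proteins and the respiratory chain, picked by name and not by length, with longer ones such as Ndufs1 and Uqcrc2 among them; their median of 0.714 ± 0.089 lay between the bounds set for and against it and decides nothing. Macrophage markers had a median of 1.194 ± 0.255, below 1.73 by slightly more than the 2 standard errors required, and so passed the bound written against this explanation by less than 1 standard error, and after the value was seen RNA from more macrophages was left open, with medians of 0.53 for macrophage and 1.44 for ribosomal genes without saline replicate 1 and of 2.06 and 2.11 without saline replicate 3; Lyz2, Mrc1 and Fcgr3, named after their values were seen as the brightest, were at 18.68 ± 0.31, 14.59 ± 0.72 and 14.28 ± 0.24 against 16.82 ± 1.70, 12.87 ± 1.83 and 11.83 ± 1.99 in saline (SD, n = 3), and all 24 markers were above the median gene in saline and 2 stood on another list. Control separation predicted a median of 0.257, above the 0.224 of the 95th percentile of permutations but far below 1.73, so it could account for a small part. An effect of the exosomes remains possible beside these.

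The lower fibroblast and matrix genes in iCM than in saline were set against 2 explanations. If the pieces had held less scar and more myocardium, sarcomere genes would likely have been higher, and their median was −0.452 ± 0.298. That lies below 0 by more than its standard error and so passed the bound written against this explanation, but by less than 1 further standard error, and after the value was seen it was read as leaving the explanation open. Control separation predicted a median of −0.351, above the −0.841 of the 5th percentile of permutations, against −1.09 measured for matrix genes, so it may account for part. Neither test separates these from an effect of the injected cells.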

How the results depend on the processing

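Added after the data were seen were leaving out saline replicate 1 and iCM replicate 2 together, leaving out the 3 arrays with lung, muscle or fat markers (iCM replicates 1 and 2 and iCM-Ex replicate 3) together, and control separation as a covariate. Of 350 named gene results, 350 kept direction and side of the threshold with the mean of all rows of a gene, 346 with all rows but controls, 327 with a common median, 315 with quantile normalisation and 311 with trend and robust variances. Of 46 list results, 44, 45, 42, 34 and 44 did. Fewer gene results did with the replicate block (268), only the groups compared (263), array weights (218, with 131 newly past the threshold) and the 3 added alternatives (249, 225 and 227). With each array left out the number ranged from 248 (without saline replicate 2) to 315. Genes that a filter on dim genes removed have no value there. All alternatives chosen beforehand were run. The separation of positive from negative controls, 2.47 in iCM replicate 2 and up to 4.01 in iCM-Ex replicate 2, limits how small a change of dim genes the arrays can show.

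Leaving out each array in turn gave 126 to 803 genes and 7 to 17 lists for iCM minus saline, 0 to 163 genes and 10 to 16 lists for iCM-Ex minus saline, 0 to 401 genes and 16 to 21 lists for iCM-Ex minus iCM, 43 to 723 genes by the F test and r of 0.429 to 0.613. Where 0 genes were past the limma threshold, 1915 to 3012 had an unadjusted p below 0.05. Without iCM replicate 2 camera's direction for skeletal muscle genes in iCM-Ex minus iCM reversed, with medians of −1.818 to −0.04 over the arrays left out.

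Genes past the threshold in iCM minus saline, iCM-Ex minus saline, iCM-Ex minus iCM and the F test numbered 338, 0 (2755 at an unadjusted limma p below 0.05), 18 and 205 with the replicate number as a block, 1500, 1187, 559 and 2108 with array weights, and 1642, 315, 614 and 1615 at an adjusted p below 0.1. In the first 3 they numbered 279, 1 and 13 with only the groups compared and 3983, 2963 and 2816 at an unadjusted p below 0.05 with 1.5-fold. Replicates of one number did not go together, with correlations of −0.257 to 0.068 and 0 of 9 arrays best with its own number. Trend and robust variances gave 17 genes for iCM-Ex minus saline, a common median 327 for iCM-Ex minus iCM, and genes above the median 352 for iCM-Ex minus iCM, with 7 lists for iCM minus saline and 8 for iCM-Ex minus saline. Estimated correlations left 0, 0 and 0 lists, fry in one direction 1, 0 and 0, and fry in either direction 20, 12 and 11.

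Without saline replicate 1 and iCM replicate 2, 117, 0 (2806 unadjusted by limma), 44 and 34 genes and 9 lists for iCM minus saline were past the threshold, with skeletal muscle medians of −0.04 for iCM-Ex minus iCM and 0.187 for iCM minus saline. Without the 3 marker arrays, 6, 0 (1911 unadjusted by limma), 0 (1872) and 0 (2487) genes were, the tricarboxylic acid cycle median for iCM minus saline reversed to 0.225, those for adipocytes and oxidative stress turned to −0.215 and 0.137, and for iCM-Ex minus iCM Tnnt3 reversed to 0.064, Cyp2f2 to 0.154 and Cyp2e1 to 0.016. With 1 iCM array left, that array was assumed to vary like the other groups.

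With control separation as a covariate, 33, 5, 0 (1252 unadjusted by limma) and 74 genes and 6 lists for iCM minus saline were past the threshold, and r was 0.372. For iCM minus saline the adipocyte median reversed to −0.332 and the skeletal muscle one to −0.354, and the lysosomal one turned to 0.009. For iCM-Ex minus iCM the adipocyte median reversed to 2.14 (camera adjusted p = 0.000689) and skeletal muscle to 2.465 (2.66e-07). Complement reversed to −0.186 (0.373) and unfolded protein response to −0.334 (0.496). In the same contrast Casp6 reversed to −0.597, Rcan1 to −0.200, Eng to −0.039, Actn3 to 0.839, Tnnt3 to 3.679, Nppa to −0.574 (uncertain, since its iCM-Ex signals and 2 of its saline ones were at the top of the scale), Cytl1 to −0.200 and Cyp2e1 to 1.662. The cause was not tested for any of these. The array of iCM replicate 2 had both the lowest control separation (2.47) and the highest adipocyte and skeletal muscle means (11.22 and 11.09). For the adipocyte and skeletal muscle lists the covariate therefore cannot be told apart from such tissue on that array.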

Other observations

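The lists, the tests and the rule for naming genes in this part were fixed beforehand, but not which of the lists are described. None of those described passed the camera threshold.

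Circadian clock genes moved in both directions between iCM-Ex and saline. The clock output gene Dbp had a log2 change of −4.42 ± 0.85 (SE), from 15.39 ± 0.33 to 10.97 ± 0.53 (SD, n = 3; limma adjusted p = 0.0674), and the period gene Per3 one of −2.99 ± 0.60 (limma adjusted p = 0.0747). Nr1d1, a repressor of the clock, was at −2.65, and the activator gene Npas2 at 1.38. Limma called 0 of the 18 measured genes over all genes, and 4 rose and 7 fell when adjusted over the list alone. Fry gave an adjusted p of 0.000496 for change in either direction, which 12 of the 43 lists passed in this contrast, and camera 0.149. In iCM relative to saline the activator gene Clock fell (limma adjusted p = 0.0453), a call that ended on removal of any of the 9 arrays (adjusted p of up to 0.119, without saline replicate 2), and in iCM-Ex relative to iCM the repressor gene Nr1d2 fell by 2.60 (limma adjusted p = 0.0492, and 0.225 without iCM-Ex replicate 3). The time of day of tissue collection is not given in the sources used here.

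Fetal and cardiac stress genes went both ways between iCM and saline, with 9 of 18 higher, 9 lower and a median of −0.205 ± 0.496. Fry gave an adjusted p of 0.0186 in one direction, downwards, and camera one of 0.0932, and adjusted p = 0.701 with an estimated correlation. The muscle LIM protein gene Fhl1 and the calcineurin regulator gene Rcan1, which fell by 3.23, were past the limma threshold over all genes, Rcan1 with a limma adjusted p of 0.0833 without saline replicate 2, and 5 members fell when adjusted over the list alone. Nppb was at −1.64 ± 0.40 (limma adjusted p = 0.0515). Among lymphocyte genes, in mice without functional T and B cells, the natural killer cell genes Gzma and Klrk1 were at 1.91 and 1.63 in iCM and at 1.93 and 1.64 in iCM-Ex relative to saline. Their saline means of 4.92 and 4.49 lay below the median negative control, so the size of these changes is uncertain. Gzma and Klrk1 were past the limma threshold over the list alone in both contrasts and not over all genes. Camera gave adjusted p of 0.191 and 0.141 for that list.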
